A study of Mus musculus with 22 samples.

How the data were processed

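RNA sequencing of sorted fetal germ cells at E16.5, RNA sequencing of whole testes at postnatal day 20 and small RNA sequencing of whole fetal testes at E16.5 were analysed. Per the labels the germ cell libraries were made after depletion of ribosomal RNA with a SMARTer stranded kit, the testis libraries with NEBNext Ultra II Directional after a DNase step and depletion of ribosomal RNA, and the small RNA libraries with the NEBNext Multiplex Small RNA kit after size selection of 15 to 40 nt. The germ cells are called gonocytes in some labels and sorted spermatogonia in others. Controls at E16.5 were Spocd1 heterozygous, the sorted germ cells of both groups were heterozygous for a Tom allele of Miwi2, and the strain was mixed. At day 20 the wildtype and the Miwi2 knockout were C57BL/6N and the Spocd1 knockout was of mixed strain.

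The deposited RNA tables hold raw counts, 1 table of reads per Ensembl gene and another of reads per repeat family at E16.5, and 1 of reads per repeat family at day 20. The deposited small RNA tables hold counts of reads per distinct sequence, library and annotation, without strand or position. In the first each sequence appears once per library with 1 annotation, and this table was used throughout. In the second a sequence with several annotations appears several times with its full count, and this table served as an alternative. A further deposited column of the first table, in a unit of its own, gives 1 value per library, the factor that brings its mature microRNA reads to the same total in every library, and it was not used. The authors list cutadapt 1.16, Bowtie 1.2.1.1, Bowtie2 2.3.4.3, HTSeq 0.11.1, HISAT2 and DESeq2 with the mm10 genome, without a role for each. The repeat library, the mismatches allowed, the order of annotation and the strand of counting are not given in the sources used here. The knockout columns of the RNA tables were tied to single samples and the control columns only to their group, and 0 columns were tied to neither.

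The gene counts came to 5048018 to 7820650 per library. The summary lines of the gene table put 17.0% to 23.6% of reads outside features, 2.63% to 4.15% in more than 1 feature, 32.1% to 36.2% as not aligned, 3.64% to 6.01% as aligned to several places and 0% as of low quality. Repeat counts came to 880956 to 1560802 per library at E16.5 and 138323 to 400974 at day 20. The small RNA reads came to 20446300, 19228165 and 18621101 in the knockout and 11651228, 15971921 and 29018628 in controls, of which 1.70% to 2.06% held an unread base. Reads of 24 to 30 nt numbered 5629164, 5803700 and 5240502 in the knockout and 4364774, 5387117 and 6778495 in controls. Between replicates the spread was above counting error in every table (lowest chi-square per degree of freedom 2.62).

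Groups, comparisons, gene lists, repeat classes, named genes and the alternatives below were fixed before the data were examined. Counts were compared with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1, as quasi-likelihood tests with robust dispersion, TMM scaling, the filterByExpr filter (a count of 10 and a total of 15) and a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the root of the test statistic. The filter left 17260 of 54838 genes, 463 of 627 families at E16.5, 232 of 303 at day 20, 768 of 870 in the piRNA window and 545 of 1247 microRNAs. TMM factors went from 0.901 to 1.07 for genes, 0.764 to 1.31 for families at E16.5 and 0.639 to 1.92 at day 20, where all 9 libraries were fitted together. Values per library are CPM scaled by TMM. Gene positions are from GENCODE vM21 on GRCm38, in which 54723 of the genes were found. Small RNA shares were compared by two-sided exact permutation tests with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. Where several classes were tested the p-values were adjusted by the Benjamini-Hochberg method, and figures were drawn with matplotlib 3.10.9. The piRNA window was 24 to 30 nt.

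The named genes are Spocd1 and Piwil4, then up to 12 rising and 12 falling called genes with the largest change among those with no overlap between the groups and a mean of at least 1 CPM. From each gene list the called members, up to 4, were named, or otherwise the 2 with the smallest unadjusted p. Of the repeat families up to 8 rising and 8 falling called ones with the largest change and a mean of at least 10 CPM were named, with every young L1 family and the 2 most abundant internal IAP families. Of the small RNA families the 5 rising and 5 falling called ones with the largest change and the 5 most abundant were named. A few genes and families outside this rule are given as chosen after their values were seen.

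Gene lists covered the piRNA pathway, DNA methylation, heterochromatin, relatives of Spocd1, germline genes linked to promoter methylation, fetal male germ cells, pluripotency, meiosis, spermatids, cell cycle, p53 and apoptosis, interferon, imprinting, Sertoli cells, fetal Leydig cells, interstitial and peritubular cells, endothelium, macrophages and leukocytes, erythroid cells, immediate early and stress genes, and mitochondrially encoded genes. Repeat classes went by family name into young L1 (L1MdA, L1MdT, L1MdTf, L1MdG and L1MdGf), old L1, IAP, other ERVK, ERVL and MaLR, and SINE. RLTR10 families were counted with IAP in the RNA tables and with other ERVK in the small RNA tables. This rule puts some families of other retrovirus classes, such as RLTR4 and RLTR6, with other ERVK. It also puts RLTR1IAP_MM, RLTR2IAP_MM and RLTR2aIAP_MM there, although their names hold IAP. Lists and classes were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry.

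The tests were tried on simulated data with known changes, 10 draws per comparison with 200 changed genes or 40 changed families. For the germ cell genes edgeR found 34.5% of 2-fold and 78.3% of 4-fold changes with 8.44% false calls, and for the families of E16.5 it found 47.0% and 88.5% with 4.24% false. At day 20 it found 83.0% and 98.5% for the Spocd1 knockout with 4.22% false, 85.0% and 95.0% for the Miwi2 knockout with 3.74% false, and 80.0% and 91.5% between the mutants with 4.72% false. In the piRNA window it found 77.5% and 99.0% with 5.61% false, and among microRNAs 40.0% and 88.5% with 6.88% false. A simulated list of 20 genes raised 2-fold or 4-fold was called, and 0 of 21 unchanged lists were. The simulated genes were drawn independently, so this cannot show false calls of lists whose genes move together.

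The alternatives tried were relative log expression scaling, DESeq2 1.42.0, no filter on low counts, a block of replicate number, a log2 change of at least 1, total counts without TMM, scaling by the gene counts, 21 to 23 nt reads as library size, windows of 25 to 29 and 23 to 32 nt, only the compared groups in the model, an estimated correlation and each library left out in turn. The comparison of microRNAs, the second small RNA table, small RNA without structural and microRNA reads, families named MLTR moved to other ERVK, and wildtype libraries split between the P20 contrasts were added after seeing the data. Raw reads were not analysed here. The overlap of ping-pong partners was not computed, since the table used gives no strand or position. For the same reason no result is limited to reads that map to 1 place.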

Results

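RNA and small RNA were measured in mouse male germ cells and testes with and without Spocd1, a gene named after the SPOC domain of its protein. Small RNA of fetal testes at E16.5 was sequenced from 3 samples of Spocd1 heterozygous controls and 3 of the Spocd1 knockout, with 6 testes pooled in each sample. RNA of germ cells sorted from testes at E16.5 came from 3 control and 4 Spocd1 knockout samples. RNA of whole testes at postnatal day 20 came from 3 wildtype, 3 Miwi2 knockout and 3 Spocd1 knockout samples, 1 testis in each. The gene counts of the E16.5 germ cells held 5048018 to 7820650 reads per library, and the repeat counts of the same libraries held 880956 to 1560802. At day 20 the repeat counts came to 138323 to 159931 per wildtype library and 301414 to 400974 per mutant library, and no gene counts were used. The small RNA table used for the main results held 11651228 to 29018628 reads per library. The labels list the replicates as separate samples, so the p-values measure the spread between samples.

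The comparison of sorted germ cells asked which genes depend on Spocd1 at the stage when fetal male germ cells remethylate their DNA. Spocd1 RNA, from a gene on chromosome 4 at 129929249 to 129957115 in GRCm38, fell from 253 ± 22.8 CPM in controls (SD, n = 3) to 66.8 ± 16.8 in the knockout (SD, n = 4). Its single libraries read 242, 237 and 279 in controls and 73.5, 81.8, 42.9 and 68.8 in the knockout, a log2 fold change of -1.92 (SE 0.20, adjusted p = 0.000118). Piwil4, which encodes the nuclear PIWI protein MIWI2, read 120, 160 and 190 CPM in controls and 138, 301, 139 and 163 in the knockout. Its log2 fold change was 0.24 (SE 0.26, adjusted p = 0.999).

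Beyond Spocd1, few genes were called at E16.5. Of 17260 genes tested, 8 rose and 37 fell, and all 45 had no overlap between the groups. In simulated data the same test found 34.5% of 2-fold changes, so smaller changes can be missed. Among all genes tested 5.61% had groups that did not overlap, where chance gives 5.71%. The 8 that rose were protein-coding genes whose changes lay between 1.23 and 1.47 on the log2 scale. Mrps14, a protein of the mitochondrial ribosome, rose from 9.51 ± 1.93 to 26.5 ± 8.47 CPM (SD, n = 3 and 4; chromosome 1, 160195215 to 160202170). Rsrc1, linked to pre-mRNA splicing, rose from 22.1 ± 4.08 to 59.9 ± 11.3, with an adjusted p of 0.00222. The gene lies on chromosome 3 at 66981390 to 67358396, antisense to Shox2, so its source is uncertain. Noct, which encodes nocturnin, rose from 23.3 ± 3.18 to 60.6 ± 20.8 CPM on the same chromosome at 51224447 to 51251644. Smarca1, an ATPase of ISWI chromatin remodelling complexes on the X chromosome at 47809368 to 47892974, rose from 36.0 ± 7.44 to 88.1 ± 18.1. Nol4 rose by 1.31, Lmbr1 by 1.24, Plxdc2 by 1.23 and the zinc finger gene Zfp951 by 1.23 on the log2 scale.

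The genes that fell were mostly low in controls and near 0 in the knockout, and 22 of the 37 were protein-coding. Gm44617 fell from 8.26 ± 0.826 to 0.125 ± 0.153 CPM, a log2 change of -5.87 (chromosome 7, 28640443 to 28645671). Gm45114 fell by 5.82 on the log2 scale (chromosome 7, 19760906 to 19762254). Cblc, a ubiquitin ligase of the CBL family, fell from 6.15 ± 2.44 to 0.336 ± 0.174 CPM close by, at 19778881 to 19796809. Gm45405, a processed pseudogene on chromosome 8 at 64910968 to 64911977, fell from 21.9 ± 2.08 to 1.72 ± 0.851 and had the smallest adjusted p, 0.000118. Serpina3c, a serine protease inhibitor gene on chromosome 12 at 104146382 to 104153870, fell from 8.16 ± 1.68 to 0.505 ± 0.517. Il3ra, the alpha chain of the interleukin 3 receptor on chromosome 14 at 14346275 to 14356011, fell from 11.1 ± 1.21 to 1.02 ± 0.393. The odorant receptor gene Olfr1307 changed by -4.77 on the log2 scale, and the noncoding genes 1700021F02Rik, Gm15704 and Gm35164 by -4.67, -3.88 and -3.51. The pseudogenes 4930519F09Rik and Gm11927 changed by -4.19 and -4.10. Several of these share sequence positions with other genes and the strand of counting is not given in the sources used here, so their source is uncertain. Noct overlaps Gm38357, Lmbr1 overlaps C79130, Gm44617 overlaps Gm44618, Gm45114 lies within Bcam, 4930519F09Rik is antisense to Themis, and Il3ra is antisense to Gm48860.

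The tests were edgeR quasi-likelihood tests, and some calls ended with a library left out while the folds stayed near. Without control library 2 the count of called genes was 21, and without the filter on low counts it was 112. Leaving out control library 2 ended the calls of Mrps14 (0.219), Noct (0.173), Nol4 (0.0986), Lmbr1 (0.104), Plxdc2 (0.0854), Zfp951 (0.0856), Olfr1307 (0.608) and 1700021F02Rik (0.0854), with the adjusted p in parentheses. Their log2 changes were then 1.38, 1.34, 1.19, 1.203, 1.35, 1.21, -4.40 and -4.93. Without control library 1 the adjusted p was 0.0553 for Mrps14, 0.0608 for Noct, 0.0720 for Plxdc2, 0.0850 for Olfr1307 and 0.294 for 1700021F02Rik. Without control library 3 it was 0.0571 for Smarca1, 0.108 for Plxdc2, 0.0727 for Zfp951, 0.130 for Olfr1307, 0.0775 for 1700021F02Rik and 0.0793 for Gm11927. On the knockout side, leaving out library 1 ended the calls of Plxdc2 (0.0985), Olfr1307 (0.0730) and 1700021F02Rik (0.0634). Olfr1307 lost its call without knockout library 2 (0.0844) and Mrps14 without library 3 (0.0584). Without knockout library 4 the values were 0.10 for Mrps14, 0.0738 for Noct, 0.0712 for Plxdc2, 0.0712 for Olfr1307 and 0.0738 for 1700021F02Rik. Over every alternative run, the adjusted p went from 3.8e-05 to 0.219 for Mrps14, 8.04e-07 to 0.173 for Noct, 9.35e-06 to 0.0986 for Nol4 and 2.65e-06 to 0.0571 for Smarca1. It went from 0.00015 to 0.104 for Lmbr1, 0.00107 to 0.108 for Plxdc2, 2.82e-05 to 0.0856 for Zfp951, 0.00287 to 0.608 for Olfr1307, 0.000278 to 0.294 for 1700021F02Rik and 1.46e-05 to 0.0793 for Gm11927. Rsrc1 kept its call in every alternative run.

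The falling genes gathered on chromosome 7. Besides Spocd1, 12 of 36 falling genes (33.3%) lay there, against 7.82% of all tested genes (one-sided Fisher's exact p = 1.06e-05, adjusted p = 0.000234 over 22 chromosomes). Of these, 10 lay between 19.8 and 30.9 Mb. These genes were chosen after their values were seen. They include Bcam, a laminin receptor gene (-3.17), Gm45114 (-5.82) and Cblc (-4.16), which lie within 100 kb of each other. Farther along came Kcnn4, a calcium-activated potassium channel gene (-2.03), Phldb3 (-1.84), the pseudogene Gm6518 (-2.37), Gm44617 (-5.87) and Capn12, a calpain gene (-1.94). The lectin genes Cd22 (-2.06) and Mag (-2.49), again neighbours, stood at the far end. The other called genes of the chromosome were BC051019 (-2.0) and Gm9165 (-3.17). Capn12, Cd22 and BC051019 are antisense to Actn4, Gm29439 and Akip1, and Gm6518 and Gm9165 overlap Samd4b and Abca16, so their source is uncertain. The 197 uncalled genes of the region had a median log2 change of -0.14, with quartiles of -0.40 and 0.04, and 72.1% of them lay below 0. The control and knockout embryos of this comparison came from a mixed strain background.

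**Figure D1:**
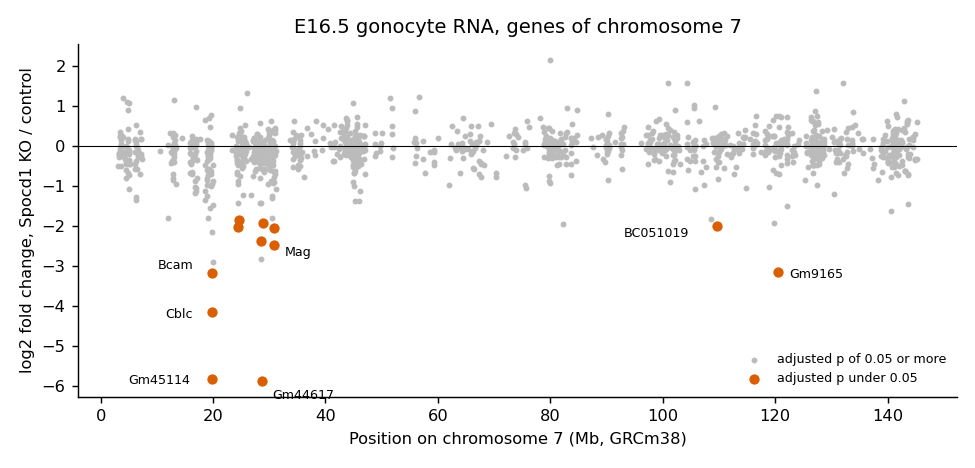
Log2 fold change of each tested gene on chromosome 7 in sorted germ cells at E16.5, Spocd1 knockout (n = 4) against control (n = 3), along the chromosome in Mb (GRCm38). Coloured points mark the 12 called falling genes, of which 10 lie between 19.8 and 30.9 Mb among uncalled genes with a median of -0.14.

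Gene lists fixed in advance were tested as groups in the same germ cells, and 0 of their members were called by edgeR or by DESeq2 over all genes. The piRNA pathway list (25 genes) had a median log2 change of 0.14 and was called upward (camera adjusted p = 0.0348), but not with an estimated correlation (adjusted p = 0.996). Its members under an unadjusted p of 0.05 were Gtsf1, a partner of PIWI proteins, at 1.01, and Exd1, a piRNA biogenesis factor, at 0.55. Germline genes linked to promoter methylation (24 of 25 measured) were called upward too, with a median of 0.24 (camera adjusted p = 0.0110), and again not with an estimated correlation (adjusted p = 0.996). Tex11, an X-linked meiotic gene, stood at 0.69 in that list and was the 1 member of any list called when adjusted over the list alone (0.0277), and Slc25a31, an ADP/ATP carrier of germ cells, stood at 0.44. Fry called 0 lists (smallest adjusted p 0.960), and Fkbp6 and Mov10l1 stand in both lists. The DNA methylation list (17 genes, median -0.10, adjusted p = 0.471) had Tet2, a dioxygenase that oxidises methylcytosine, at -0.61 and the glycosylase gene Tdg at -0.53. Heterochromatin factors (26 of 28, median -0.03 with an upward test, adjusted p = 0.931) had the histone methyltransferase gene Suv39h2 at 0.48 and the HUSH complex gene Pphln1 at -0.59. Relatives of Spocd1 with TFIIS-like or SPOC domains (8 genes, median -0.08, adjusted p = 0.931) had Dido1 at -0.26 and Spen at -0.21, both above an unadjusted p of 0.05. Fetal male germ cell markers (25 of 27, median 0.06, adjusted p = 0.920) had Sall1 at -0.65 and Ctcfl at -0.47. Pluripotency genes (12 of 16, median 0.00, adjusted p = 0.992) had Nanog at -0.91 and Tdgf1 at 0.74. Meiosis genes (24 of 25, median 0.12, adjusted p = 0.920) had the cohesin gene Rec8 at -0.43 and Hormad1 at 0.33, and spermatid genes (7 of 15, median -0.45, adjusted p = 0.471) had Akap4 at -1.15 and Tnp1 at 0.68.

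None of the lists for cell state or for other cell types of the testis was called. Cell cycle genes (26, median 0.01, adjusted p = 0.992) had Cdkn1c at 0.62 and Cdk1 at -0.51, and p53 and apoptosis genes (20, median 0.01, adjusted p = 0.992) had Perp at 0.68 and Gtse1 at -0.37. In both the median and the test differed in sign. Interferon and nucleic acid sensing genes (21 of 30, median -0.11, adjusted p = 0.920) had Oasl2 at -1.01 and Oas2 at 0.82. Imprinted genes (27 of 32, median 0.04, adjusted p = 0.810) had Peg10 at 0.50 and Cdkn1c at 0.62. Markers of Sertoli cells, the somatic cells that nurse the germ line (13 of 20, median 0.07, adjusted p = 0.920), had Sox9 at -0.75 and Inhbb at 0.58. Markers of fetal Leydig cells, the steroid producers (9 of 15, median -0.02 with an upward test, adjusted p = 0.931), had Lhcgr at -0.78 and Cyp17a1 at 0.65. Interstitial and peritubular markers (15 of 20, median -0.03, adjusted p = 0.894) had Maf at 1.07, and endothelial markers (11 of 14, median 0.03, adjusted p = 0.920) had Cdh5 at 0.38 and Pecam1 at -0.28. Macrophage and leukocyte markers (8 of 15) had the highest median of any list, 0.54, without a call (adjusted p = 0.118), with Mrc1 at 0.85 and Fcer1g at 0.89. Erythroid markers (5 of 14, median 0.06 with a downward test, adjusted p = 0.810) had Slc4a1 at -1.09 and Epor at -0.53. Immediate early and stress genes (16 of 20, median 0.06, adjusted p = 0.920) had Gadd45b at -1.56 and Junb at 1.36. Mitochondrially encoded genes (11 of 13, median 0.21, adjusted p = 0.920) had mt-Nd4 at 0.31 and mt-Co3 at -0.25. At an unadjusted p under 0.05 the number of members was 3 in the immediate early list, 1 each in the p53, interferon, imprinted, macrophage, erythroid, DNA methylation, meiosis and spermatid lists, 2 each in the heterochromatin and fetal germ cell lists, and 0 in the rest but the called ones.

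At E16.5 the same germ cells were compared for RNA of repeat families, which asked whether transposons escape control early. Of 463 families tested, 2 rose and 17 fell, all 19 with no overlap between the groups, against 3 and 40 scaled by the gene counts and 9 and 29 by DESeq2. Groups did not overlap in 17.1% of all families, where chance gives 5.71%. RLTR1IAP_MM, an endogenous retrovirus family, rose from 1605 ± 709 to 7306 ± 2872 CPM of repeat counts (SD, n = 3 and 4; log2 change 2.19, SE 0.39, adjusted p = 0.00735). IAPEZI, the internal part of intracisternal A particles, which are mouse retrotransposons active today, rose from 14022 ± 5773 to 48154 ± 18193 (log2 change 1.78, SE 0.42, adjusted p = 0.0419). A related internal family, IAPLTR1a_I_MM, had a log2 change of 1.26 that missed the threshold (adjusted p = 0.0594). RLTR6I_MM, related to murine leukaemia virus, fell from 2746 ± 132 to 1141 ± 117 (adjusted p = 0.000296). RLTR10B2 fell by 1.40, ZP3AR by 2.00 and ERVB2_1A-I_MM by 1.79 on the log2 scale. ERVB4_2-I_MM and ERVB4_3-I_MM fell by 1.40 and 2.46, MURVY-int, a family of the Y chromosome, by 1.45, and IAPEY5_LTR by 1.09.

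None of the 13 young L1 families, a class set by name that includes LINE elements still mobile in mice, was called at E16.5 by edgeR. Their log2 changes went from -0.22 for L1MdTf_III to 0.31 for L1MdGf_I, 0 of them had an unadjusted p under 0.05, and DESeq2 also called 0. Young L1 made up 28.3% ± 3.67 of the repeat counts in controls (SD, n = 3) and 25.2% ± 5.15 in the knockout (SD, n = 4). The share of all IAP families was 5.43% ± 1.34 in controls and 10.2% ± 3.98 in the knockout, with overlapping libraries. Of 37 IAP families 1 rose and 7 fell, or 5 and 9 adjusted over the list alone, and the list was not called (median -0.15, camera adjusted p = 0.0975). By name this list holds RLTR10 families and leaves out RLTR1IAP_MM, whose rise counts among other ERVK. Other ERVK families (216) had 1 rise and 7 falls with a median of -0.03 (adjusted p = 0.463), a sign that turned to 0.00 under relative log expression scaling. Old L1 families (59) had 1 fall and a median of 0.06, which was -0.07 without TMM (adjusted p = 0.406). The 46 ERVL and MaLR families had a median of 0.02, which was -0.10 without TMM, and 0 calls by edgeR or DESeq2 with 1 at an unadjusted p under 0.05 (adjusted p = 0.463). SINE families, short retrotransposons, were called as a list of 27 with a median of 0.22, or 0.01 without TMM (camera adjusted p = 0.0180). That call did not hold with an estimated correlation (adjusted p = 0.907), and 0 of its members were called by edgeR or DESeq2, with 1 at an unadjusted p under 0.05. The young L1 list had a median of -0.06 with an upward test (camera adjusted p = 0.760), and fry called no class in 1 direction at E16.5 (smallest adjusted p 0.227). Its mixed test, which takes changes either way, called old L1 (adjusted p = 0.0105), IAP (0.000126) and other ERVK (3.35e-05).

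Scaling by the gene counts moved the median log2 change of all families by -0.29 and total counts alone moved it by -0.14. With total counts alone the calls of RLTR1IAP_MM (0.0767), IAPEY5_LTR (0.108) and IAPEZI (0.131) ended, at log2 changes of 2.06, -1.19 and 1.65, near those with TMM. Without control library 1 there were 8 calls, and the adjusted p was 0.0521 for MURVY-int, 0.0521 for RLTR1IAP_MM, 0.0962 for IAPEY5_LTR and 0.180 for IAPEZI. Without control library 2 there were 7 calls, and the values were 0.0585 for MURVY-int, 0.0830 for RLTR1IAP_MM, 0.0745 for IAPEY5_LTR and 0.202 for IAPEZI. IAPEY5_LTR (0.0679) and IAPEZI (0.0715) also lost their calls without control library 3, and IAPEZI did so without knockout library 3 (0.0905) and library 4 (0.129). IAPLTR1a_I_MM gained a call without knockout library 1 (0.0145) and library 2 (0.0362), by DESeq2 (0.000258), without the filter on low counts (0.0399) and without TMM (0.0323). Over every alternative run the adjusted p went from 1.79e-05 to 0.202 for IAPEZI, 1.21e-07 to 0.0830 for RLTR1IAP_MM, 0.000163 to 0.108 for IAPEY5_LTR, 5.8e-08 to 0.0585 for MURVY-int and 0.000258 to 0.242 for IAPLTR1a_I_MM.

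At postnatal day 20, when spermatogenesis has reached meiosis, the question was which transposons are derepressed without Spocd1 and whether loss of Miwi2 gives the like. RNA of several young L1 families was far higher in both mutants. L1MdTf_I rose from 10123 ± 83.4 CPM of repeat counts in wildtype to 174263 ± 26096 in the Spocd1 knockout (SD, n = 3 each). In the Miwi2 knockout it rose to 184626 ± 19422 (adjusted p = 1.04e-09 and 8.61e-10). L1Md_Gf_5end rose by 4.26 on the log2 scale in the Spocd1 knockout (SE 0.13) and 4.39 in the Miwi2 knockout (SE 0.13), and L1MdTf_II by 4.14 and 4.24. L1MdA_I rose by 3.32 and 3.62, and L1_MM, counted by its name with old L1, by 3.17 and 3.47. MMERVK10C, an ERVK provirus family, rose from 8124 ± 353 to 67002 ± 10899 in the Spocd1 knockout and to 44956 ± 2042 in the Miwi2 knockout. IAPEZI rose from 11659 ± 31.0 to 46271 ± 12633 in the Spocd1 knockout and to 89719 ± 9503 in the Miwi2 knockout. Spocd1 knockout library 3 stood apart from libraries 1 and 2 (chi-square per degree of freedom 173.1 and 172.5, against 11.6 between those), and the 3 libraries read 47975, 32873 and 57966 for IAPEZI. IAPA_MM rose by 3.21 and 4.29, the satellite GSAT_MM by 3.08 and 3.28, and RLTR1IAP_MM by 2.19 and 3.13, in the Spocd1 and Miwi2 knockouts. Young L1 took 20.9% ± 0.242 of all repeat counts in wildtype, 49.2% ± 5.31 in the Spocd1 knockout and 49.0% ± 1.89 in the Miwi2 knockout (SD, n = 3 each).

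**Figure D2:**
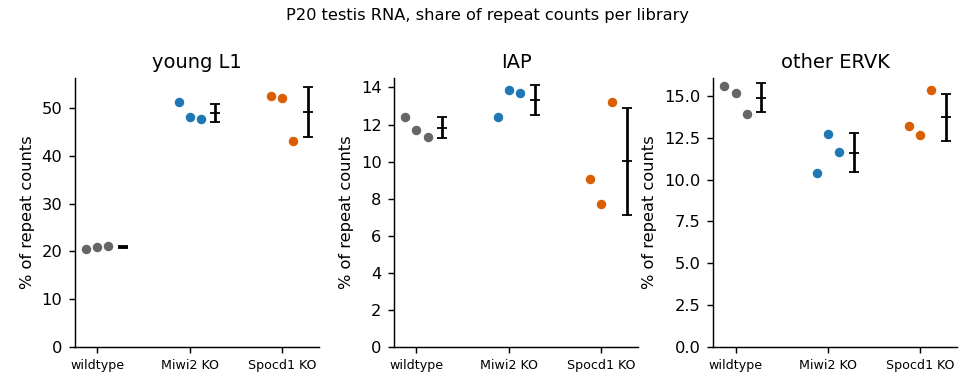
Share of repeat counts (percent) taken by young L1, IAP and other ERVK families in whole testes at day 20, with each library as a point and bars for mean ± SD (wildtype, Miwi2 knockout and Spocd1 knockout, n = 3 each). Young L1 lies at 20.59% to 21.04% in wildtype and at 43.1% to 52.5% in the Spocd1 knockout.

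Other families fell in both mutants. IAPLTR3_I, the internal part of the IAPLTR3 group of IAP elements, fell from 14271 ± 2502 CPM in wildtype to 185 ± 6.45 in the Spocd1 knockout and 198 ± 38.0 in the Miwi2 knockout. The log2 changes were -6.27 (SE 0.17, adjusted p = 2.31e-11) and -6.18 (SE 0.16, adjusted p = 2.39e-11). IAPLTR3, the terminal repeat of that group, changed by -4.88 and -5.12. RLTR9D2 changed by -2.69 and -3.65 and RLTR30B_MM by -4.43 and -3.35, in the Spocd1 and Miwi2 knockouts. IAPEY3_LTR (-2.78) and RLTR9A2 (-5.55) were among the largest falls of the Spocd1 knockout, and RLTR41B (-4.46), RLTR41A2 (-3.80) and RLTR1F_Mm (-3.33) among those of the Miwi2 knockout. IAPEY3_LTR also fell in the Miwi2 knockout (-2.39), and RLTR41A2 (-2.39) and RLTR1F_Mm (-2.44) also fell in the Spocd1 knockout. In the Spocd1 knockout RLTR41B had 0 counts in each library, against 19 to 44 in wildtype, and was at least 9.62-fold lower. RLTR20D_MM had 0 counts there, against 5 to 13, and was at least 2.94-fold lower. RLTR9A2 had 0 counts in the Miwi2 knockout, against 18 to 30, and was at least 7.53-fold lower. These bounds take a floor of 3 counts per library, and intervals and floors of this kind cover counting error only.

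By edgeR, 47 of 232 families rose and 55 fell in the Spocd1 knockout, all 102 with no overlap between the groups. In the Miwi2 knockout 57 rose and 69 fell, 121 of 126 with no overlap. Groups did not overlap in 61.2% and 62.9% of all families, where chance gives 10%. Of the 13 young L1 families 10 rose in the Spocd1 knockout, or 11 adjusted over the list alone, and 11 in the Miwi2 knockout. The young L1 list was called in both, with medians of 1.43 and 1.6, or 0.15 and 0.18 without TMM (camera adjusted p = 1.37e-06 and 4.85e-07). With an estimated correlation the adjusted p was 0.156 and 0.132, and by fry, which asks whether a list changed without comparing it to the others, 0.000169 and 5.79e-05. L1MdA_II rose by 2.28 and 2.59, L1MdA_III by 1.53 and 1.75, and L1MdGf_II by 1.43 and 1.6. L1MdTf_III rose by 1.34 and 1.41, which was 0.12 and -0.01 without TMM. L1MdGf_I rose by 1.27 and 0.99, which turned to -0.04 and -0.43 without TMM, and L1MdA_IV by 0.63 and 0.71, which turned to -0.62 and -0.71. L1MdA_V had values of 0.19 (adjusted p = 0.0637) and 0.26 (adjusted p = 0.0144), which turned to -1.06 and -1.16 without TMM. The uncalled L1MdA_VI stood at -0.04 and -0.05 and L1MdA_VII at -0.09 and 0.00, or -1.28 and -1.46, and -1.33 and -1.41, without TMM. Of 33 IAP families, without RLTR1IAP_MM, 16 rose and 6 fell in the Spocd1 knockout and 17 rose and 8 fell in the Miwi2 knockout. Their medians of 0.49 and 0.56 turned to -0.75 and -0.86 without TMM (camera adjusted p = 0.0180 and 0.0158, or adjusted p = 0.265 and 0.255 with an estimated correlation and 0.0121 and 0.00465 by fry). Other ERVK families (110) had 8 rises and 40 falls, and 11 rises and 48 falls, with medians of -0.29 and -0.40. Their list was called in both (camera adjusted p = 5.13e-05 and 2.38e-05), but not with an estimated correlation (adjusted p = 0.11 and 0.0906, or 0.00129 and 0.000628 by fry). Of 8 SINE families 3 and 7 rose, with medians of 0.20 and 0.31 that turned to -1.05 and -1.11 without TMM (camera adjusted p = 0.199 and 0.0821, fry adjusted p = 0.0487 and 0.0140). Of 28 old L1 families 1 rose and 4 fell, and 2 rose and 5 fell, with medians of -0.15 and -0.14 (camera adjusted p = 0.330 and 0.479). L1_MM was among these rises in both mutants. ERVL and MaLR families (16) had medians of -0.01 in both with an upward test, which turned to 0.04 and 0.06 under relative log expression scaling (camera adjusted p = 0.823 and 0.928).

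All values at day 20 are relative to the other repeats, since no gene counts were used. Without TMM the median of all families moved by -1.23 in the Spocd1 knockout and -1.41 in the Miwi2 knockout, and the calls became 12 up and 188 down, and 13 up and 199 down. L1MdTf_I then still rose by 2.84 and 2.76, L1Md_Gf_5end by 3.01 and 2.96, MMERVK10C by 1.80 and 1.05 and IAPEZI by 0.77 and 1.52. GSAT_MM lost its call (adjusted p = 0.0577 and 0.0569), as did L1MdGf_II (0.342 and 0.263) and L1MdA_III (0.245 and 0.0895). IAPLTR1a_I_MM, which rose by 1.02 and 1.82, came to -0.21 and 0.40. In the Miwi2 knockout L1MdGf_I lost its call without Miwi2 knockout library 2 (0.0553) and L1MdA_V without wildtype library 3 (0.0534). L1MdA_V gained a call in the Spocd1 knockout without Spocd1 knockout library 3 (0.00545), by DESeq2 (0.0149) and under relative log expression scaling (0.0243). Over every alternative run the highest adjusted p in the Spocd1 and Miwi2 knockouts was 0.195 and 0.0534 for L1MdA_V, 0.835 and 0.0553 for L1MdGf_I, 0.529 and 0.969 for L1MdTf_III, and 0.275 and 0.0389 for IAPLTR1a_I_MM, and the lowest of each was under its value with TMM. The Spocd1 knockout was of mixed strain, and the wildtype and Miwi2 knockout were C57BL/6N.

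**Figure D3:**
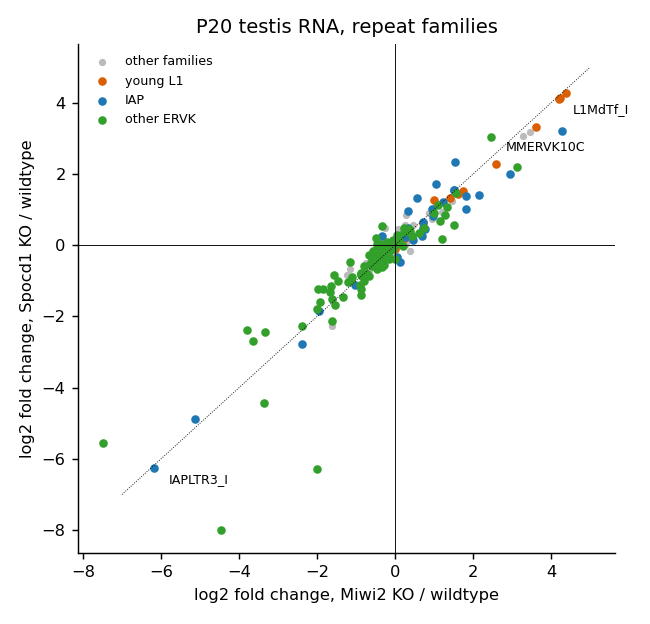
Log2 fold change of each repeat family against wildtype at day 20, Miwi2 knockout on the x axis and Spocd1 knockout on the y axis (n = 3 per group), with the line of equal change dotted. Points gather along the line (r = 0.934), 3 families with 0 counts in a mutant are drawn at fitted values, which depend on the model, and without TMM the median moved by -1.23 in the Spocd1 knockout and -1.41 in the Miwi2 knockout.

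The 2 mutants changed much the same families in whole testes, where a change in the cells that make up the testis was not tested. Across 232 families the log2 changes had a Pearson r of 0.934 and a Spearman rho of 0.934, with a covariance of 1.91. Families are not independent replicates, and both contrasts share the wildtype libraries. Simulated mutants without any change that shared their controls gave a mean r of 0.489, from 0.328 to 0.651, and a covariance of at most 0.0459. Of 47 and 57 rising families 44 were shared, where chance for independent lists gives 11.5. Of 55 and 69 falling families 52 were shared, where chance gives 16.4, and 0 were called in opposite directions. After seeing the data the wildtype libraries were split, 1 for one mutant and 2 for the other, in all 6 ways. Pearson's r was then 0.895 to 0.925, Spearman's rho 0.839 to 0.881 and the covariance 1.83 to 1.90. The simulated mutants without any change had a mean of 0 families called in both, which does not show what shared controls add to real calls. The shared calls were not counted again in these splits, so part of their excess is not separated from the shared controls.

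Set directly against each other, the mutants differed in 10 of 232 families, all with no overlap between the groups. The Spocd1 knockout was of mixed strain and the Miwi2 knockout of the wildtype's strain. Strain and genotype therefore cannot be told apart in these differences. IAPEZI was lower in the Spocd1 knockout than in the Miwi2 knockout by -0.96 on the log2 scale (SE 0.18, adjusted p = 0.00979). IAPLTR1a_I_MM (-0.80), IAPLTR1_Mm (-0.74), RLTR1IAP_MM (-0.95), ERVB4_1-I_MM (-0.92) and RLTR46B (-1.01) were lower too. MMERVK10C was higher in the Spocd1 knockout, by 0.58 (SE 0.13, adjusted p = 0.0197), as were IAPEY5_I by 0.82, IAPEY3_I by 0.60 and ERVB7_1-I_MM by 0.50. Of the 13 young L1 families 0 were called by edgeR, 0 had an unadjusted p under 0.05, and DESeq2 called 0. Their log2 differences went from -0.31 for L1MdA_II to 0.28 for L1MdGf_I. Groups did not overlap in 17.7% of families, where chance gives 10%. No repeat class was called in 1 direction (smallest camera adjusted p 0.258, fry 0.431), while the mixed test of fry called IAP (adjusted p = 5.63e-07) and other ERVK (3.01e-05).

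Several of these calls ended with a library left out, and total counts alone moved the median of all families by 0.18. Without Miwi2 knockout library 1 the count was 5, and IAPEY3_I, ERVB7_1-I_MM, MMERVK10C, RLTR46B and RLTR1IAP_MM each had an adjusted p of 0.0866. Without Miwi2 knockout library 2 ERVB7_1-I_MM (0.0519), RLTR46B (0.0884) and RLTR1IAP_MM (0.239) lost their calls. Without Miwi2 knockout library 3 the count was 4, and the values were 0.0508 for IAPLTR1_Mm and IAPEY3_I, 0.0590 for ERVB7_1-I_MM, 0.0693 for MMERVK10C, 0.155 for RLTR46B and 0.0925 for RLTR1IAP_MM. Without Spocd1 knockout library 1 RLTR1IAP_MM came to 0.203, and without library 2 ERVB7_1-I_MM came to 0.0543 and RLTR46B to 0.160. Without Spocd1 knockout library 3 RLTR46B came to 0.0695, and L1MdGf_I was called with a difference of 0.57 (0.0152). MMERVK10C, RLTR46B and RLTR1IAP_MM came to 0.0548 without wildtype library 2, and RLTR1IAP_MM to 0.0525 without wildtype library 3. With only the compared groups in the model 1 family was called, ERVB4_1-I_MM. Without TMM RLTR1IAP_MM (0.223), RLTR46B and IAPLTR1_Mm (0.125 each) and IAPLTR1a_I_MM (0.0615) lost their calls, as did RLTR46B by DESeq2 (0.0767). IAPEYI (0.00355) and IAPEY_LTR (0.0219) gained calls without TMM, so that 6 families were higher and 2 lower in the Spocd1 knockout, against 4 and 6 with TMM. Over every alternative run the adjusted p went from 9.76e-09 to 0.0112 for ERVB4_1-I_MM, 5.49e-05 to 0.0685 for IAPEZI, 0.000331 to 0.148 for MMERVK10C and 5.49e-05 to 0.239 for RLTR1IAP_MM. It went from 1.3e-05 to 0.0615 for IAPLTR1a_I_MM, 0.000335 to 0.125 for IAPLTR1_Mm, 0.00023 to 0.0590 for IAPEY5_I, 0.00132 to 0.0866 for IAPEY3_I, 0.000968 to 0.0866 for ERVB7_1-I_MM and 0.0349 to 0.160 for RLTR46B.

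Small RNA of whole fetal testes addressed whether piRNAs, the small RNAs bound by PIWI proteins, are still made without Spocd1. Their broad features did not separate the groups. Reads of 24 to 30 nt made up 28.6% ± 1.39 of small RNA in the knockout and 31.5% ± 7.31 in controls (SD, n = 3 each, two-sided exact permutation p = 0.6). The lengths peaked at 27 nt in this window in every library, with 5.42% ± 0.313 and 6.06% ± 1.80 of reads. The log2 ratio of these reads to those of 21 to 23 nt was -0.692 ± 0.106 and -0.577 ± 0.444 (exact permutation p = 0.7). A uridine at base 1, the mark of primary piRNAs, was present in 68.3% ± 0.888 and 69.0% ± 3.41 of them (exact permutation p = 0.8). An adenine at base 10, the mark of ping-pong partners, was present in 32.5% ± 0.226 and 32.5% ± 2.64 (exact permutation p = 1). Repeats took 61.3% ± 1.13 and 61.8% ± 3.86 of the window (exact permutation p = 0.9). With 3 against 3 samples the smallest p possible is 0.1, and control library 3 stood apart with 23.4% of reads in the window, against 37.5% and 33.7% in the other controls.

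**Figure D4:**
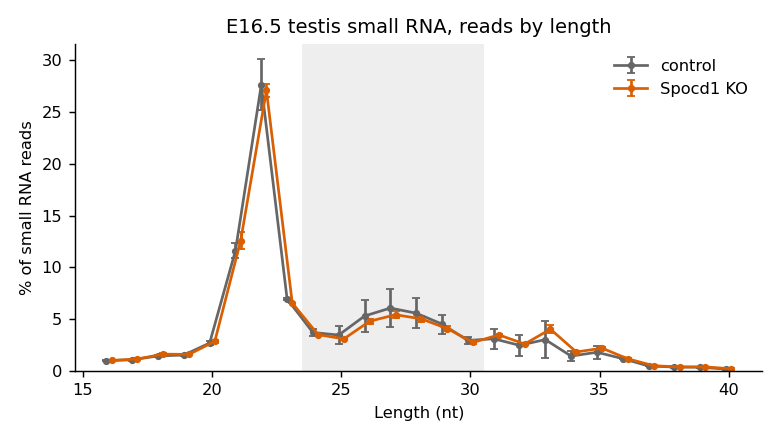
Share of small RNA reads (percent) at each length in nt in fetal testes at E16.5, as mean ± SD of 3 Spocd1 knockout and 3 control libraries, with the window of 24 to 30 nt in grey. Both groups peak at 22 nt, with 27.1% ± 0.631 and 27.6% ± 2.45, and again at 27 nt.

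Within the piRNA window no class share passed a test. In the small RNA the RLTR10 families were counted with other ERVK and not with IAP. IAP families took 12.5% ± 0.453 of the reads in the knockout and 8.87% ± 1.01 in controls, with no overlap (difference 3.6 points, two-sided exact permutation p = 0.1, adjusted p = 0.65 over 13 classes). Other ERVK families took 7.40% ± 0.342 and 10.7% ± 1.77, also with no overlap (difference -3.32 points, exact permutation p = 0.1, adjusted p = 0.65). The internal family IAPEz-int held 462709, 508983 and 439488 of the 681615, 753096 and 645444 IAP reads in the knockout. In controls it held 180173, 168268 and 373608 of 378301, 429463 and 675055. The other IAP reads took a lower share of the window in every knockout library than in any control library. The rise of the IAP class thus came from this family. Young L1 took 8.78% ± 1.05 and 10.03% ± 1.67 (exact permutation p = 0.6), and old L1 13.9% ± 1.26 and 13.8% ± 0.843 (exact permutation p = 0.9). SINE reads made up 8.43% ± 0.557 and 7.99% ± 0.550 (exact permutation p = 0.4), ERVL and MaLR 5.59% ± 0.332 and 5.55% ± 0.983 (exact permutation p = 1), and genes 15.1% ± 0.528 and 14.2% ± 1.48 (exact permutation p = 0.4).

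**Figure D5:**
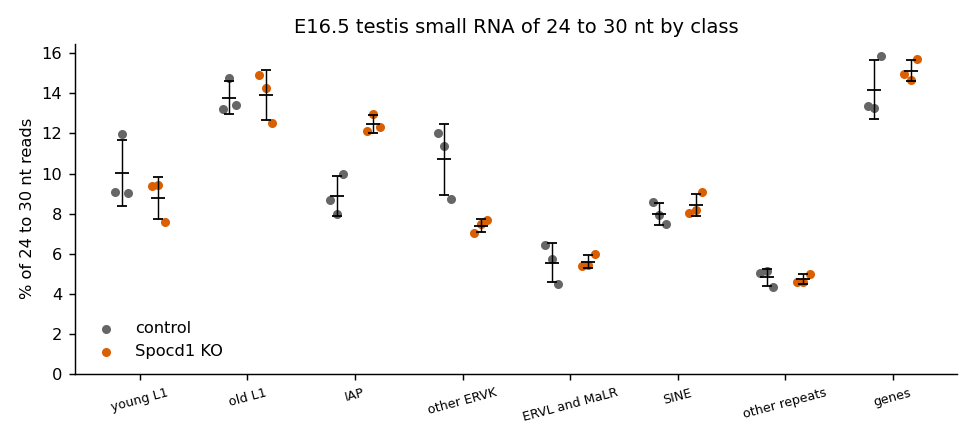
Share of 24 to 30 nt reads (percent) by class of origin in fetal testes at E16.5, each library as a point with mean ± SD for Spocd1 knockout and control (n = 3 each). IAP lies at 12.1% to 13.0% in the knockout and at 7.97% to 9.96% in controls.

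Counted by family, 39 of 768 repeat families rose and 121 fell in the piRNA window, 159 of the 160 with no overlap between the groups. Groups did not overlap in 36.7% of all families, where chance gives 10%. RLTR4_MM-int, related to murine leukaemia virus, fell from 9249 ± 974 to 1455 ± 159 CPM of repeat reads (log2 change -2.67, SE 0.13, adjusted p = 1.4e-05). ERVB4_2-I_MM-int changed by -3.17, ERVB4_3-I_MM-int by -3.07, RLTR45-int by -2.72 and RLTR46A2 by -2.59. RLTR11D rose from 732 ± 73.1 to 1676 ± 22.2 CPM, and MER89-int, LTR40c, MLT1E and MLT1E1A, old mammalian LTR families, rose by 1.67, 1.69, 1.63 and 1.22. IAPEz-int, the most abundant family, rose from 67893 ± 27397 to 143596 ± 7193 (log2 change 1.08, SE 0.28, adjusted p = 0.0254), and MMERGLN-int by 0.73 (adjusted p = 0.0107). Small RNAs of the abundant L1 families L1Md_F2 (0.17, adjusted p = 0.584), L1Md_T (-0.06, adjusted p = 0.849) and L1Md_A (-0.05, adjusted p = 0.910) were not called.

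Of 25 IAP families, here without RLTR10, 2 rose and 11 fell. The list was called downward with a median of -0.45 (camera adjusted p = 0.000254, or adjusted p = 0.313 with an estimated correlation). Of 271 other ERVK families 16 rose and 76 fell, and the list was called downward with a median of -0.15 (camera adjusted p = 0.000206, or adjusted p = 0.313 with an estimated correlation). Old L1 (114, median 0.09, or -0.02 without TMM), ERVL and MaLR (132, 0.06, or -0.06 without TMM) and SINE (31, 0.13, or 0.01 without TMM) were called upward, with camera adjusted p of 0.00846, 0.0184 and 0.00839. With an estimated correlation these calls did not hold either (adjusted p = 0.313, 0.432 and 0.313). Their called members were 1 up and 3 down, 9 up and 7 down, and 1 up. Fry called IAP (adjusted p = 0.0147), other ERVK (0.0190) and SINE (0.0107), but not old L1 (0.120) or ERVL and MaLR (0.3001). Young L1 (4 families, median -0.06) had 0 calls by edgeR, 1 at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.750).

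Scaling and single libraries bore on the rises. Total counts alone moved the median by -0.12 and the 21 to 23 nt reads as library size by -0.33, under which 1 family rose and 55 fell. Then RLTR11D (0.280), MER89-int (0.0737), LTR40c (0.0621), MLT1E (0.0647), MLT1E1A (0.342), MMERGLN-int (0.745) and IAPEz-int (0.0818) lost their calls. Without knockout library 2 there were 101 calls. IAPEz-int was not called without knockout library 1 (0.128), 2 (0.0939) or 3 (0.0957) or without control library 1 (0.0821) or 2 (0.0671). MMERGLN-int lost its call without knockout library 1 (0.0628), 2 (0.0550) or 3 (0.0585). Over every alternative run the adjusted p went from 0.000163 to 0.128 for IAPEz-int and 2.8e-05 to 0.745 for MMERGLN-int. For the families that rose, the lowest was 6.11e-20 for RLTR11D, 2.34e-11 for MER89-int, 9.54e-11 for LTR40c, 1.26e-12 for MLT1E and 5.34e-10 for MLT1E1A, and the highest was the value just given.

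Mature microRNAs, compared as a second class of small RNA after seeing the data, gave no call. By edgeR 0 of 545 passed, with 33 at an unadjusted p under 0.05, and DESeq2 called 0, while without the filter on low counts 2 were called. The abundant miR-99a-5p had a log2 change of 0.47 (adjusted p = 0.619), miR-10b-5p of -0.16, let-7c-5p of 0.13, miR-26a-5p of 0.02 and miR-148a-3p of 0.02.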

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

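Among the 4 knockout libraries of sorted germ cells at E16.5, 10 of 87 checked genes and families had 1 library far from the other 3 by Dixon's test, where chance picks about 1 in 20 groups. Groups of 3 cannot be checked this way. The test takes no account of counting error, which matters for low genes. Gm11927 read 0.481 CPM in library 2, against 0.157 to 0.196 in the others, or 4 counts against 1 in each. Piwil4 read 301 in the same library, against 138 to 163. Tex11 read 59.2 in library 1, against 75.3 to 76.9. In that library Lhcgr read 3.50, against 0.481 to 0.942, and Slc4a1 read 1.29, against 2.41 to 2.54. The repeat family L1MdA_II read 46721 CPM there, against 13414 to 18680. Library 3 was apart for Tnp1 with 13.1 CPM, against 4.24 to 4.33, for Sox9 with 3.13, against 5.34 to 5.78, and for ERVB2_1A-I_MM with 94.7, against 58.8 to 64.9. Tdgf1 read 1.88 in library 4, against 3.87 to 4.11.

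In the Spocd1 knockout 7 repeat families moved in opposite directions in every sample at the 2 stages, in sorted germ cells at E16.5 and in whole testes at P20. The difference between the stages was not tested, and without TMM some of the later values change sign. ERVB4_1B-I_MM had a log2 change of -1.09 at E16.5 and 1.48 at P20, or 0.22 without TMM. ERVB4_1B-LTR_MM had -0.94 and 1.06, or -0.18 without TMM. ERVB4_3-I_MM had -2.46 and 0.84, or -0.39 without TMM. IAP5-Mm_I had -0.82 and 1.39, or 0.13 without TMM. IAPEY4_I had -0.79 and 1.55, or 0.30 without TMM. IAPLTR4_I had -0.66 and 0.49, or -0.75 without TMM. RLTR10B2 had -1.40 and 1.32, or 0.12 without TMM.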

How the results depend on the processing

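Tests of the mature microRNAs, of the second small RNA table, of small RNA without structural reads, of the class of MLTR families and of split wildtype libraries were chosen after seeing the data. Of the 102 named genes and families that were called, 58 kept their direction and their call in every alternative and with every library left out. Of the counts, list results and shares under other settings 62 stayed near the reported value, 9 were lower, 7 higher and 1 moved. Without the filter on low counts the calls were 112 for E16.5 genes, 16 between the P20 mutants and 2 for microRNAs, and the correlation between the P20 mutants fell to 0.706. DESeq2 called 38 families at E16.5. A log2 change of at least 1 left 12 families at E16.5, 58 in the Spocd1 and 64 in the Miwi2 knockout at P20, 1 between the mutants and 69 in the piRNA window, since it removes small changes by construction. Scaling by the gene counts gave 43 families at E16.5, and the 21 to 23 nt reads as library size gave 56 in the piRNA window. Only the compared groups in the model, which leaves fewer samples to estimate the spread, gave 1 family between the mutants. With an estimated correlation 0 gene lists and 0 repeat classes were called. Total counts without TMM gave 200 calls in the Spocd1 and 212 in the Miwi2 knockout at P20, and they turned the sign of several families because all values moved down together. In the Spocd1 knockout IAPLTR1a_I_MM came to -0.21, L1MdA_IV to -0.62, L1MdGf_I to -0.0389 and L1MdA_V to -1.06. In the Miwi2 knockout L1MdTf_III came to -0.00737, L1MdA_IV to -0.71, L1MdGf_I to -0.43, L1MdA_V to -1.16 and the uncalled L1MdA_VII to -1.41. For the other changes given here the cause was not tested. For named genes and families other settings kept 832 values, ended 38 calls, gave 8 and turned 9, and 3 class shares of the piRNA reads moved. With a library left out 1142 values kept their call, 73 lost it and 4 gained it. With a library left out, the calls went from 21 to 49 for E16.5 genes, 7 to 24 for E16.5 families, 92 to 112 and 104 to 129 for the Spocd1 and Miwi2 knockouts at P20, 4 to 14 between them, 101 to 188 in the piRNA window and stayed at 0 for microRNAs. With a wildtype library left out, the correlation of the mutants went from 0.894 to 0.935. The knockout minus control difference went from -6.98 to 0.0753 points for the share of 24 to 30 nt reads, -0.358 to 0.0783 for their log2 ratio to 21 to 23 nt reads, -2.55 to 0.665 points for uridine at base 1 and -2.65 to 1.04 points for the repeat share. Libraries of the same replicate number correlated weakly, at -0.0853 to 0.135. The RNA control columns were tied only to their group and each comparison had 3 pairs, so pairing is neither shown nor excluded. With a block of replicate number the calls were 51 for E16.5 genes, 17 for E16.5 families and 105, 123 and 7 in the P20 comparisons. They were 127 in the piRNA window, 0 for microRNAs and 3 for gene lists. These lists were the 2 called before and interstitial and peritubular markers, which were downward. Under the block none of the 3 was called with an estimated correlation (camera adjusted p = 0.923 for each). The ping-pong overlap and its alternatives were not run, since the table gives no strand or position, nor was a limit to reads that map to 1 place. Depth limits the low genes most, since several falling genes had 0 to 4 counts per knockout library.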

Other observations

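Of the tests below, those of neighbouring genes, of scaling and strain for IAPLTR3, and of the annotation order and the 100 most abundant sequences for IAP small RNAs, and all of microRNAs were chosen only after the result was seen. At E16.5 the RNA of a repeat family and its small RNAs moved alike in the Spocd1 knockout. Across 268 families with both measurements Spearman's rho was 0.346 and Pearson's r was 0.414, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. Without the 2 farthest families r was 0.389. Of the 14 families called in both, 13 fell in both and 1, IAPEZI with its small RNA counterpart IAPEz-int, rose in both. Most calls were falls, 17 of 19 in RNA and 121 of 160 in small RNA, which alone makes joint falls frequent. The agreement due to chance was not computed. The families of murine leukaemia virus type, RLTR6I_MM in RNA (-1.27) and RLTR6-int in small RNA (-2.56), fell together, as did ERVB4_2-I_MM (-1.40 and -3.17), MURVY-int (-1.45 and -1.24), RLTR10B2 (-1.40 and -2.17) and IAPEY5_LTR (-1.09 and -2.55). These pairs were chosen after their values were seen. At P20 the RNA changes did not follow the fetal small RNA changes across 153 families, with rho 0.0179 (permutation p = 0.824), r -0.0524 (permutation p = 0.517) and -0.0411 without the 2 farthest. Of 39 families called in both, 26 had the same direction, again without a chance share beside it. Families are not independent replicates. Small RNA abundance that follows the RNA present at the same stage is a hypothesis that these values allow. The sorted cells and the whole testes, different samples, cannot settle it. The E16.5 embryos were of mixed strain, and whether strain bears on the families that moved alike was not tested.

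In the piRNA window MMERVK10C-int, chosen after its values were seen, fell by 0.94 (adjusted p = 0.000383), the counterpart of the provirus family whose RNA rose at P20. Among IAP small RNAs, in values that passed no test, adenine stood at base 10 in 43.4% ± 0.919 of knockout reads against 38.8% ± 0.905 and uridine at base 1 in 69.5% ± 0.699 against 72.0% ± 0.289 (SD, n = 3 each, exact permutation p = 0.1 for both, the smallest possible). Among other ERVK reads adenine at base 10 stood at 36.8% ± 0.322 against 38.8% ± 0.777 (exact permutation p = 0.1), and among young L1 reads at 47.8% ± 0.436 against 49.2% ± 1.34 (exact permutation p = 0.3).

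The gathering of falling E16.5 genes on chromosome 7 was weighed against technical sources. Counting genes within 100 kb once left 9 of 32 falling loci there (one-sided Fisher's exact p = 0.000573, adjusted p = 0.0126), which argues against shared reads of neighbours as the whole cause. Removing the trend on GC content left the median of the falling genes of chromosome 7 at -2.37 (SD 1.48), from -2.43 (SD 1.46). That trend was weak over all genes (Spearman's rho -0.121) and too small to account for falls of this size. These genes were richer in GC, with a median of 56.6% against 49.1% of tested genes and 51.4% of chromosome 7. The gathering was not tested again without the trend, so GC content stays open there. The uncalled genes of the full span had a median of -0.0418 (834 genes), which argues against a lost copy of the whole region. In the narrower stretch of 10 genes, chosen after seeing it, the uncalled median was -0.14 and 72.1% of the genes were below 0, a small shift that stays open. A linked stretch of another strain's chromosome may differ between the mixed-strain groups, which was not tested and stays open beside an effect of Spocd1.

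The near loss of IAPLTR3_I RNA in both P20 mutants was weighed next. Without any scaling the mutant nearer to wildtype had a log2 ratio of -6.23, so scaling does not account for it. The Miwi2 knockout, of the wildtype's strain by the labels, showed -6.18, which argues against the mixed strain of the Spocd1 knockout as the cause. The lowest wildtype library held 56.1 times the counts of the highest mutant library, with 3253 to 4308 counts in wildtype and 39 to 58 in the mutants, so no single library made it. A change in the cells that make up the testis, or an effect of the mutations on these copies, stays open and was not tested.

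The higher share of IAP among piRNA-sized reads of the knockout, which came from IAPEz-int, was weighed as well. In the table that lists every annotation the lowest knockout library was still 1.99 points above the highest control, which argues against the order of annotation, and IAP reads with neither base mark differed by 0.0207 points, which argues against fragments of longer RNA. With each sequence counted once the groups overlapped, at -0.221 points, as a rise of few abundant sequences would give. Without the 100 most abundant IAP sequences the gap was 1.602 points, so these alone do not carry it, and the reads per IAP sequence were 4.55 to 4.8 in the knockout and 2.94 to 3.95 in controls. More reads of many of the same sequences may therefore underlie the share, and a higher output from IAPEz-int RNA at this stage stays open.

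Other splits of the same libraries into groups of these sizes were run for each count. Of 35 splits of the E16.5 germ cells 2 gave as many genes as the real one, so chance is not excluded for the 45 called genes. The other split, of control library 1 with knockout libraries 1, 3 and 4 against the rest, called 150 genes, several times the real count, which points to a structure of the samples other than genotype. For the repeat families of E16.5 only the real split, 1 of 35, gave as many as its 19 calls. That share is under 0.05, which argues against chance but does not exclude it with so few splits. The highest other count was 12, in the split that called 150 genes. For 3 against 3 samples 10 splits are too few for a share under 0.05. The real counts and the highest others were 102 and 0 for the Spocd1 knockout at P20, 126 and 0 for the Miwi2 knockout, 10 and 0 between the mutants, 160 and 0 in the piRNA window, and 0 and 2 for microRNAs. The likeness of the mutants at P20, with an r of 0.934, or 0.706 without the filter on low counts, held at 0.895 or more with no wildtype library in both contrasts. Part of the overlap of their calls, which was not counted in those splits, may come from the shared libraries.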
